A study of Mus musculus with 8 samples.

How the data were processed

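RNA from mouse bone marrow cells sorted by flow cytometry was measured on 8 Affymetrix arrays, 4 of L-GMPs from leukaemic mice and 4 of GMPs from normal marrow. GMP is the usual short name of the granulocyte-macrophage progenitor, and the leukaemia carries the genotype label HoxA9+Meis1 AML. Replicates carry the letters A to D in each group. Groups were taken from the sample titles. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

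Per the labels' protocols, total RNA was extracted with Trizol and cleaned on a column, and per the submitters' processing notes the values were made with RMA, whose version is not given in the sources used here. RMA corrects the background, normalizes arrays to each other and summarises the probes of a probe set. The deposited values are intensities on a linear scale, from 3.54 to 29746.73, with 1 column per array and 0 unused columns. The scale was read from the values. The labels name a whole transcript sense labelling assay, whereas the probe sets are those of the Affymetrix mouse genome array with probes toward the 3' end of transcripts. This mismatch could not be settled here, so the strand and position that the labelled target covers are unknown. Per array, the lower quartile of log2 intensity was 3.65 to 3.75, the median 5.24 to 5.49 and the upper quartile 7.39 to 7.46. No background level, detection call, scan date or batch was used, and the number of arrays limits the precision.

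Log2 was taken of the deposited intensities. Of 45101 probe sets, 64 control probe sets were left out. Of the others, 34945 had exactly 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Entrez identifiers matched 34741 of the single-symbol probe sets to the RefSeq gene table of GRCm38.p6, with 0 symbols changed, and 204 kept the symbol of the annotation. No build was named with the values and no coordinates are given. Each gene was represented by the probe set with the highest mean over all 8 arrays, which left 18193 genes. Bright and dim probe sets of a gene are named by that mean. A probe set can thus be chosen through high values in a single group, and those chosen for Hoxa9 and Mycn were the dimmest of their gene in GMPs. Probe sets of a gene can disagree: of 1230 genes past the threshold with several probe sets, 14 had probe sets past the threshold in opposite directions, among them Hoxa9, Mycn and Hmga2.

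L-GMP was compared with GMP by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on group alone, a 2-sided test and Benjamini-Hochberg adjustment over all 18193 genes at 0.05. Fold changes are L-GMP minus GMP on the log2 scale, with the standard error (SE) of the moderated fit. Adjusted p-values of genes are from this test, and those named for a second probe set of a gene come from the fit of all probe sets. Groups are described by mean and SD over 4 arrays. For each of 37 gene lists, camera with a preset correlation of 0.01 tested whether the members moved against all other genes, adjusted over the 37 lists. It called 10 lists. With a correlation estimated per list camera called 0 (5 had an unadjusted p under 0.05). Fry, which tests whether members move on balance in a single direction without comparing them with other genes, called 15 lists. Its mixed form, which tests for change in either direction, called 37. Of 907 list entries, 820 were found on the array. Members past the threshold are counted over all genes tested and, in second place, adjusted over the list alone.

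Before the data were examined, the groups, tests, lists, alternatives and naming rule were fixed. The rule named the 15 genes with the largest rise and the 15 with the largest fall among genes past the threshold whose groups did not overlap, leaving out predicted, immunoglobulin, T cell receptor and olfactory genes and small RNAs. It also named Hoxa9, Meis1, the gate antigens, up to 4 members of each list with the largest changes among those past the threshold, and the member of each cell type list with the highest mean over all arrays, which counts against members that fell. Where no member of a list passed, the member with the largest change was named. A further 41 genes were added, each marked in the text as chosen after its values were seen. The alternatives were 2 other scalings between arrays, 2 filters on dim genes, the mean of a gene's probe sets, every probe set on its own, a trended robust prior, array weights, the replicate letter as a block, no prior, limma's treat at a fold of 1.5, 3 other set tests, and each array left out in turn. Leaving out L-GMP replicate B and GMP replicate D together was added after seeing the data.

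The fit was tested on simulated data for L-GMP against GMP over 18193 genes. Values were drawn around each gene's mean with its pooled SD within groups. It recovered 82% of 100 genes changed by 1 on the log2 scale and 98% of 100 changed by 2, with 7 false calls. Other computations used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.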

Results

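The arrays compared gene expression in L-GMPs, progenitors sorted from mice with a HoxA9+Meis1 acute myeloid leukaemia, with that in GMPs sorted from normal mouse bone marrow. The comparison asks how leukaemic cells of the GMP gate differ from their normal counterpart. There were 4 arrays per group, and values are log2 RMA intensities.

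L-GMPs and GMPs differed in 2193 of 18193 genes (12.1%), of which 870 were higher and 1323 lower in L-GMPs. At least 2-fold differences were found in 690 genes, 196 higher and 494 lower. At least 4-fold differences were found in 51 genes that rose and 174 that fell. With a single probe set for each gene, the largest falls under the naming rule were in Gja1, Ppic and Smo, and the largest rises in Hpgd and Mycn. The groups did not overlap in 3318 genes (18.2%), where chance gives 2.86%. The first principal component held 59.5% of the variance and separated the groups. The second (11.4%) set L-GMP replicate B apart from the other L-GMP arrays, and the third (8.79%) set GMP replicate A apart from the other GMP arrays. Correlations across all 45037 probe sets other than controls, which are not independent replicates, were 0.983 to 0.994 within groups and 0.967 to 0.974 between them. GMP replicate D had a difference between the 3' and 5' control probe sets of Gapdh of 2.74, against 1.46 to 1.76 on the other GMP arrays. For Actb this difference was 0.64, against 0.13 to 0.42. The Gapdh group mean was 1.87 ± 0.60 (SD, n = 4) in GMPs, replicate D included, and 1.40 ± 0.13 (SD, n = 4) in L-GMPs. The Gapdh group difference had an exact permutation p of 0.114 (2-sided, smallest possible 0.029). The direction of small changes depended on scaling. Of the genes past the threshold, 39.7% were higher in L-GMPs, against 70.1% of 3084 after centring each array on its median and 49.5% of 2531 after quantile normalization. Centring moved the median fold change of all genes from 0.01 to 0.15, so small changes hold only relative to that shift. Leaving out GMP replicate B gave 1411 genes, leaving out GMP replicate D 1425 and leaving out GMP replicate A 2388.

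The genes of the leukaemia's label behaved differently between probe sets. Hoxa9, a homeobox transcription factor, rose by 4.82 (SE 0.29, 28.3-fold, adjusted p = 2e-06) in its brighter probe set, with L-GMP at 11.6 ± 0.74 and GMP at 6.79 ± 0.04 (SD, n = 4). In that probe set the L-GMP arrays lay between 10.9 and 12.3 and the GMP arrays between 6.74 and 6.84. Its dimmer probe set fell by 6.66 (SE 0.15, adjusted p = 1.85e-09), from 9.42 ± 0.26 in GMPs to 2.76 ± 0.16 in L-GMPs. That L-GMP mean lies below the 10th percentile of every array (2.84 to 2.92), so the size of the fall is uncertain. The mean of the 2 probe sets had a change of -0.92, the opposite sign. Meis1, the homeobox partner of HOXA9, fell in all 3 probe sets, with a change of -3.05 (SE 0.20, adjusted p = 4.33e-06) in the brightest and of -2.07 and -1.47 in the others. The arrays do not show which part of the transcripts these probe sets read, so neither gene checks the group labels fully.

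**Figure D1:**
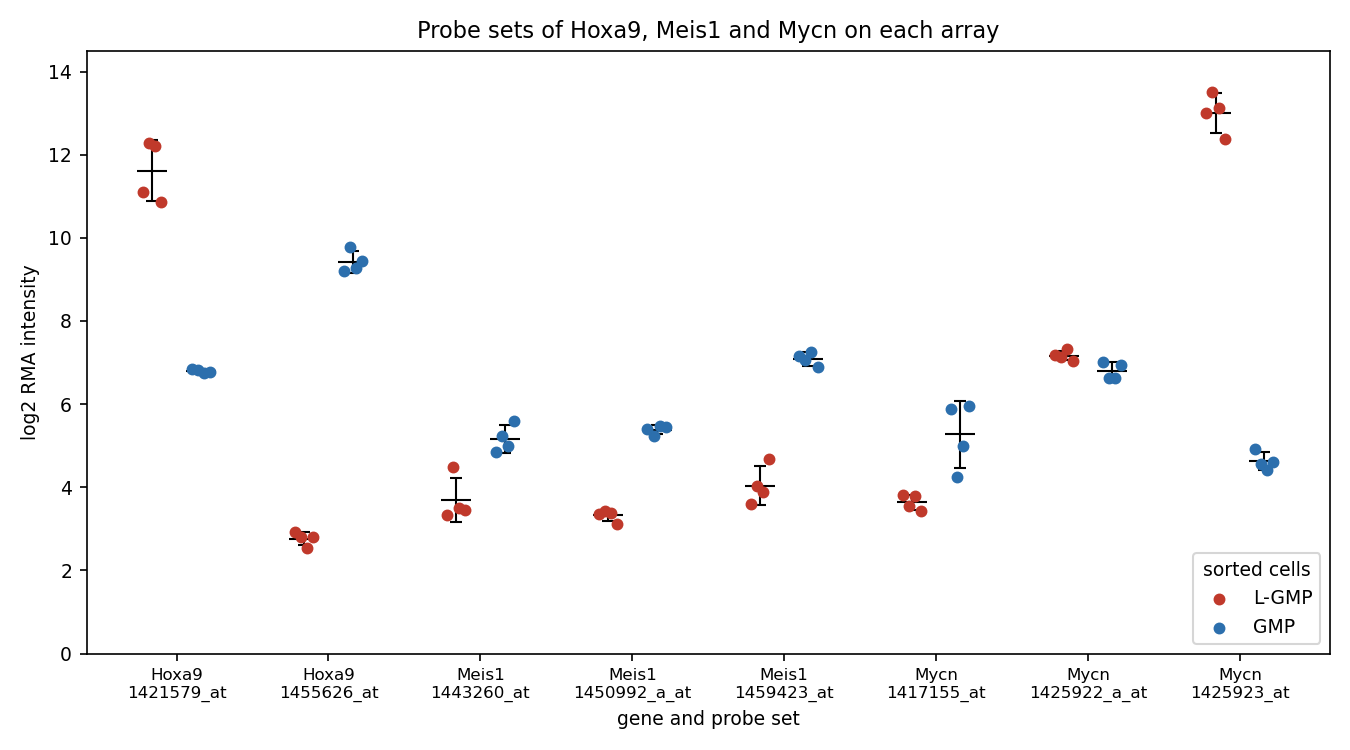
Log2 RMA intensity (vertical axis) of each probe set of Hoxa9, Meis1 and Mycn (horizontal axis) on the 4 L-GMP and 4 GMP arrays. Points are arrays, and black bars are the group mean with its SD. The 2 Hoxa9 probe sets change in opposite directions, the 3 Meis1 probe sets change by -3.05 to -1.47, and the 3 Mycn probe sets change by 8.37, 0.37 and -1.63.

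Of 21 measured Hox cluster genes, 1 rose (Hoxa9) and 4 fell (1 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.445). Its median of -0.06 was 0.09 after median centring, 0.04 after quantile normalization and -0.62 without the dimmest 25% of genes, where 4 of 8 fell and 1 rose (adjusted p = 0.0914). With every probe set tested the list was called (adjusted p = 0.0341, and 0.0341 to 0.631 over all alternatives). Hoxa5 fell by 1.05 (SE 0.14, adjusted p = 0.000719) and Hoxb3 by 0.82 (SE 0.12, adjusted p = 0.0012). Hoxa3 fell by 1.53 and Hoxa7, chosen after its values were seen, by 0.42. Neither call was firm, and the mean of the Hoxa3 probe sets changed by -0.60. Hoxa3 lost its call without any single array except L-GMP replicate B (adjusted p 0.0793 to 0.1). Hoxa7 lost it without L-GMP replicate A or C or GMP replicate A, B or D (0.051 to 0.0841) and under both other scalings (0.0157 to 0.113 over all alternatives). Among 27 cofactors and reported targets of HOXA9 and MEIS1, 4 rose and 7 fell (4 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.711). With every probe set tested it was called (adjusted p = 0.0322, and 0.0322 to 0.91 over all alternatives). Flt3, a receptor tyrosine kinase of early progenitors and leukaemia, rose by 3.29 (SE 0.27, 9.76-fold). Dach1, a transcriptional cofactor, fell by 3.29 (SE 0.15, adjusted p = 2.38e-07). The other rises besides Hoxa9 were Ccl3, by 1.90, and Pbx3, by 0.82, chosen after its values were seen. Pbx3 lost its call without L-GMP replicate D or GMP replicate C or D (adjusted p 0.06 to 0.0818), and Ccl3 without L-GMP replicate A, C or D or GMP replicate B or C (0.0549 to 0.0715).

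The largest rises were in Hpgd, the enzyme that inactivates prostaglandins, and in Mycn, a MYC family transcription factor. Hpgd rose by 8.59 (SE 0.21, 385-fold, adjusted p = 2.96e-09), from 4.09 ± 0.48 to 12.7 ± 0.13 (SD, n = 4). Mycn rose by 8.37 (SE 0.21, 331-fold) in its brightest probe set, from 4.63 ± 0.22 to 13 ± 0.47 (SD, n = 4). That probe set was brightest only through the L-GMP arrays, since in GMPs the other Mycn probe sets were higher (5.27 and 6.80). The Mycn probe set with the lowest mean over all arrays fell by 1.63 (adjusted p = 0.0104), and the remaining one had a change of 0.37 (adjusted p = 0.0897). F7, coagulation factor VII, rose by 5.09 and Klhl41 by 4.80. Slfn4 rose by 4.43, and Cd177, a neutrophil surface protein, rose by 4.28 (SE 0.39, adjusted p = 5.17e-05). Gpnmb, a glycoprotein of macrophages, rose by 3.93. Colec12, Gem, Sgip1 and Slc4a8 rose by 4.05, 3.67, 3.54 and 3.27, Colec12 from a GMP mean near the floor (2.36). The GMP means of Klhl41 (3.23) and Gem (3.59) also lay below the lower quartile of every array (3.65 to 3.75). The sizes of the rises of Colec12, Klhl41 and Gem are therefore uncertain. Igf2bp3, a fetal RNA-binding protein, rose by 3.42 (SE 0.38), and Hmga2, a chromatin protein of fetal and tumour cells, rose by 3.52 (SE 0.49, adjusted p = 0.00103) in its brightest probe set. The mean of the Hmga2 probe sets gave -0.01, since they disagree in direction. Averaging the probe sets also lowered the rise of Mycn to 2.37, of Sgip1 to 2.01 and of Slc4a8 to 0.76.

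The largest falls were in Gja1, the gap junction protein connexin 43, in Ppic and in Smo, the Hedgehog signal transducer. Gja1 fell by 6.23 (SE 0.15, adjusted p = 2.96e-09), from 8.69 ± 0.31 to 2.46 ± 0.13 (SD, n = 4). Ppic, a cyclophilin, fell by 6.19, and Smo fell by 6.15 (SE 0.11, adjusted p = 4.55e-10). The L-GMP means of Gja1, Smo and Bex1 (2.46, 2.57 and 2.66) lie below the 10th percentile of every array (2.84 to 2.92), so the sizes and the order of the falls are uncertain. Prom1, which encodes the progenitor antigen CD133, fell by 5.75 (SE 0.24). Grb10, an imprinted adaptor of growth factor receptors, fell by 5.20, Bex1 by 5.21 and Ctla2a by 5.28. Nkg7, a granule membrane protein, fell by 4.91 (SE 0.36). The ubiquitin ligase gene Nedd4 fell by 5.09 (SE 0.48). Rab38, Ak4 and Dnajc6 fell by 5.14, 4.82 and 4.79. In the mean of a gene's probe sets the changes were smaller for Smo (-3.48), Grb10 (-2.71), Ak4 (-2.51) and Dnajc6 (-3.08). The change of Gja1 was -6.34 to -4.59 over all alternatives. The remaining genes of the 15, Prg2, Pf4 and Ms4a2, belong to the lineage lists.

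Of 26 measured markers of stem cells and multipotent progenitors, 0 rose and 11 fell (1 and 17 adjusted over the list alone), with a median change of -0.77 (-0.96 to -0.39 over all alternatives). Angpt1, a ligand of the receptor Tek, fell by 3.13 (SE 0.20, adjusted p = 3.12e-06), Tek fell by 2.48 and the related receptor Tie1 fell by 2.01. Vwf, which the megakaryocyte list also holds, fell by 1.8, and Gfi1b, chosen after its values were seen, fell by 1.43. Both were lowest among GMPs in replicate B (5.11 and 5.47), as Pf4 was. Camera gave adjusted p = 6.91e-07, and adjusted p = 0.0536 with an estimated correlation. The call was also lost when the dimmest 50% of genes were left out (adjusted p = 0.0607, and 5.05e-09 to 0.0607 over all alternatives). That filter removed the fallen Angpt1, Tek, Tie1, Vwf and Gfi1b themselves, through their mean over all arrays. Of the 7 measured gate antigens, 1 rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.736). This list was fixed beforehand and may hold antigens that the sort did not use. Kit, the stem cell factor receptor, fell by 0.96 (SE 0.14, adjusted p = 0.0012), while Flt3 rose. Cd34 had a change of -0.20, Fcgr3 of 0.01, Fcgr2b of 0.11, Cd48 of -0.06 and Il7r of 0.73, none past the threshold. Il7r passed it without L-GMP replicate B (change 0.98, adjusted p = 0.0265, and 0.0265 to 0.288 over all alternatives).

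Haematopoietic transcription factors changed in both directions. Of 32 measured, 5 rose and 5 fell (6 and 6 adjusted over the list alone; list adjusted p = 0.879). Bcl11a, a transcriptional repressor of fetal globin genes that lymphoid development requires, fell by 4.06 (SE 0.16, 16.7-fold, adjusted p = 9.8e-08). Tal1, needed for the stem and erythroid programmes, fell by 3.52 (SE 0.15), Ikzf2 (Helios) by 3.41 (SE 0.12) and Gata1 by 1.68 (SE 0.13). Among the rises, the Mycn value rests on the single probe set above. Lyl1 rose by 0.56 (SE 0.09) and Gfi1b fell by 1.43 (SE 0.27), both chosen after their values were seen. Egr1, Cebpb and Ikzf1 rose by 2.21, 0.52 and 0.41, the last 2 chosen after their values were seen. Egr1 lost its call without L-GMP replicate C or GMP replicate B or C (adjusted p 0.0615 to 0.0794). Cebpb lost it without L-GMP replicate A or C or GMP replicate A, B or C (0.0691 to 0.0951), and Ikzf1 without L-GMP replicate A, C or D or GMP replicate C or D (0.0648 to 0.0962).

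Of 21 primary granule and GMP genes, 7 fell and 1 rose (9 and 3 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.472 with an estimated correlation). Without the dimmest 50% of genes the list had adjusted p = 0.0607 (0.00146 to 0.472 over all alternatives). After median centring 3 rose and 5 fell, with a median of -0.04 in place of -0.18. Nkg7 led the falls, followed by Fcnb, a ficolin of granulocytes, which fell by 2.32 (SE 0.39, adjusted p = 0.00323). Elane, neutrophil elastase, fell by 1.75 (SE 0.37, adjusted p = 0.0127), though its call ended under the trended robust prior (adjusted p = 0.053, and 0.00257 to 0.0532 over all alternatives). Csf3r, the G-CSF receptor, fell by 1.16 (SE 0.17). Csf2rb, a cytokine receptor subunit chosen after its values were seen, rose by 0.77 (SE 0.11). Mpo (myeloperoxidase), the member with the highest mean over all arrays, fell by 0.39, a call lost without L-GMP replicate A, GMP replicate B or GMP replicate C (adjusted p 0.0516 to 0.0592) and after centring on the median (0.101, and 0.00133 to 0.101 over all alternatives). Of 22 secondary granule and mature neutrophil genes, 5 fell and 1 rose (8 and 2 adjusted over the list alone). The list was not called (adjusted p = 0.0989), but passed without L-GMP replicate A (0.00574), without GMP replicate C (0.0277) and after median centring (0.00751), and ranged from 0.00574 to 0.801 over all alternatives. S100a8, a calcium-binding protein of neutrophils, fell by 3.82 (SE 0.67, adjusted p = 0.00425) and Wfdc21 fell by 2.29. Cxcr2, the neutrophil chemokine receptor, fell by 1.37, while Cd177 rose. The other members that fell, Padi4, which fell by 1.12, and Chil1, which fell by 1.10, were chosen after their values were seen. Chil1 lost its call without L-GMP replicate C or D or GMP replicate B or D (adjusted p 0.062 to 0.0921). Anxa1, highest over all arrays, had a change of -0.27 (adjusted p = 0.251).

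The monocyte and macrophage list was called higher in L-GMPs by camera with the preset correlation, though not with an estimated one. Of 28 measured, 11 rose and 1 fell (15 and 1 adjusted over the list alone), with a median change of 0.57 (0.53 to 1.04 over all alternatives). Cd68, a lysosomal protein of macrophages, rose by 2.48 (SE 0.18, 5.58-fold, adjusted p = 9.92e-06), and the pore-forming Mpeg1 by 1.93 (SE 0.21). Slpi rose by 1.78 and Ctss (cathepsin S) by 1.69. F13a1, highest in the mean over all arrays, rose by 1.57 (SE 0.10, adjusted p = 2.45e-06), from 10.5 ± 0.07 to 12.1 ± 0.11 (SD, n = 4). Camera gave adjusted p = 6.91e-07, and adjusted p = 0.185 with an estimated correlation. The 1 member that fell was Cx3cr1, chosen after its values were seen, by 0.75. The Cx3cr1 call was lost under both other scalings (adjusted p 0.0124 to 0.0796 over all alternatives) and without L-GMP replicate A, C or D or GMP replicate B (0.0538 to 0.0796). The dendritic cell list had 1 rise among 18 members, Flt3, and 0 falls (1 and 0 adjusted over the list alone; adjusted p = 0.119), against 4 rises after median centring and 2 after quantile normalization. It was called with every probe set tested (adjusted p = 0.0303), without the dimmest 50% of genes (median 0.42, 0.0316) and by fry (0.00781), with 0.00781 to 0.409 over all alternatives. Its highest member over all arrays, Cst3, had a change of 0.17 (adjusted p = 0.348).

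Camera with the preset correlation, but not with an estimated one, called the eosinophil, basophil and mast cell list lower in L-GMPs. Of 19 measured, 0 rose and 13 fell (0 and 14 adjusted over the list alone), with a median change of -1.68 (-3.55 to -1.54 over all alternatives). The eosinophil granule genes Prg2, Epx and Prg3 fell by 5.20 (SE 0.55), 4.77 (SE 0.61) and 3.93 (SE 0.50). Ms4a2, a chain of the IgE receptor, fell by 4.95 (SE 0.21, adjusted p = 1.52e-07), and from outside the rule, chosen after their values were seen, Fcer1a fell by 3.51 and Hdc, histidine decarboxylase, by 3.01. Mcpt8, a basophil protease, was highest in the mean over all arrays, though not among GMPs, and had a change of -0.46 (adjusted p = 0.253). Camera gave adjusted p = 4.01e-12, and adjusted p = 0.0536 with an estimated correlation. The GMP arrays differed widely in the eosinophil granule genes (SD 1.56 for Epx, 1.21 for Prg3 and 1.13 for Prg2) and little in Gata1 (0.105) and Hdc (0.185). Epx ranged from 7.47 to 10.9 among them, highest in GMP replicate B.

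The megakaryocyte and erythroid lists were called lower with the preset correlation. Of 17 megakaryocyte and platelet markers, 0 rose and 5 fell (0 and 6 adjusted over the list alone; median -0.39, adjusted p = 0.000676, and adjusted p = 0.472 with an estimated correlation). Pf4 (platelet factor 4) fell by 5.10 (SE 0.57, adjusted p = 0.000229) and Rab27b fell by 2.24 (-1.03 in the mean of its probe sets). Vwf, the von Willebrand factor, fell by 1.8 and Itga2b, an integrin of platelets, by 1.68 (SE 0.19). Gp5, chosen after its values were seen, fell by 0.49, a call lost after centring on the median (adjusted p 0.00753 to 0.1 over all alternatives) and without L-GMP replicate A, C or D or GMP replicate A, B or D (0.0618 to 0.0845). Itgb3, highest over all arrays, had a change of 0.36 (adjusted p = 0.494). Pf4 ranged from 7.20 in GMP replicate B to 10.4 in GMP replicate A, so GMP replicate B was the lowest for Pf4 and the highest for Epx. Without the dimmest 50% of genes the megakaryocyte list was not called (adjusted p = 0.306, and 7.79e-06 to 0.472 over all alternatives). That filter removed the fallen Rab27b, Vwf and Gp5, while Pf4 and Itga2b stayed. Of 21 erythroid markers, 6 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.23, adjusted p = 0.035, and adjusted p = 0.489 with an estimated correlation). Car2, carbonic anhydrase 2, fell by 4.32 (SE 0.22, adjusted p = 5.02e-07) and Gata1, the erythroid and eosinophil regulator, fell by 1.68. Hbb-b2, a globin gene, fell by 1.76 (SE 0.40), or -0.84 in the mean of its probe sets, and lost its call without L-GMP replicate B and GMP replicate D together (adjusted p = 0.0526). Car1 had a change of -1.8, a call lost without any single L-GMP array or GMP replicate C or D (0.0528 to 0.0885). The rises were the metallothioneins Mt1, by 1.27 (SE 0.14), and Mt2, by 1.42, both chosen after their values were seen. Mt2 lost its call without L-GMP replicate C or D or any 1 GMP array (adjusted p 0.0513 to 0.111). The erythroid call was lost without L-GMP replicate A (adjusted p = 0.075), L-GMP replicate D (0.071) or GMP replicate A (0.0969). It was also lost under quantile normalization (0.0777) and array weights (0.0602), and the list turned to a median of 0.16 (adjusted p = 0.784) without the dimmest 50% of genes, with 0.00751 to 0.784 over all alternatives. Hba-a2, highest over all arrays, had a change of 0.19 (adjusted p = 0.275).

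**Figure D2:**
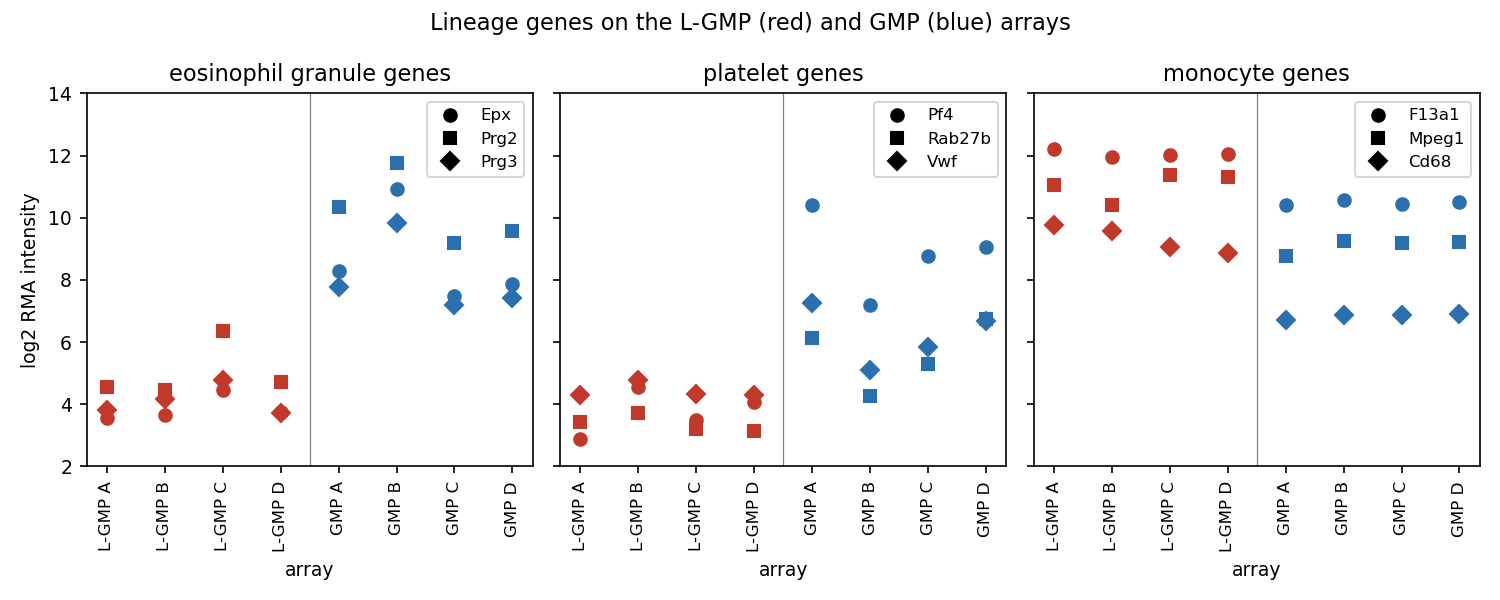
Log2 RMA intensity (vertical axis) of 3 eosinophil granule, 3 platelet and 3 monocyte genes on each array (horizontal axis), with L-GMP arrays in red and GMP arrays in blue and a symbol per gene. Epx is highest in GMP replicate B at 10.9, where Pf4 is lowest among GMP arrays at 7.20, while F13a1 is higher on every L-GMP array than on any GMP array.

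None of the lists of lymphoid, endothelial and stromal markers was called by camera or by the directional form of fry. Of 18 B lymphoid markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone; adjusted p = 0.738), against 3 and 2 after median centring and 1 and 2 after quantile normalization. These were Cd72, by 1.66 (SE 0.24), and Rag2, by 1.43 (SE 0.19). Of 19 T and NK cell markers, 1 rose (0 rose and 0 fell adjusted over the list alone; adjusted p = 0.711). This was Cd8b1, by 0.62, near the dim end of the array at 3.68 ± 0.28 in L-GMPs, a call lost without L-GMP replicate A, GMP replicate B or GMP replicate C (adjusted p 0.0589 to 0.086). Of 17 endothelial and stromal markers, 1 rose and 2 fell (2 and 3 adjusted over the list alone; adjusted p = 0.79), against 4 and 2 after median centring and 3 and 2 after quantile normalization. Vcam1, an adhesion molecule, fell by 1.66 (SE 0.32), and Emcn fell by 0.71, a call lost without GMP replicate B or D (adjusted p 0.0541 to 0.0559). Cav1 rose by 1.46, a call lost without GMP replicate C (0.0511). Cd79b, Cd247 and Pdgfrb, highest over all arrays, had changes of -0.40, -0.26 and 0.34, none past the threshold, while Cd247 and Pdgfrb had -0.03 and -0.02 in the mean of their probe sets.

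With the preset correlation camera called the interferon-stimulated list lower and the MHC class I list higher in L-GMPs, and it called neither with an estimated one. Of 32 interferon-stimulated genes, 14 fell and 2 rose (20 and 2 adjusted over the list alone), with a median change of -0.54. Rtp4 fell by 1.84 (SE 0.21, adjusted p = 0.000221), Gbp2, a guanylate-binding protein, fell by 1.70 and Ddx58, which encodes the RNA sensor RIG-I, fell by 1.52. In the mean of their probe sets Rtp4 and Ddx58 had changes of -0.86 and -0.87. Usp18 fell by 1.45, a call lost without L-GMP replicate A, B or C or GMP replicate B, C or D (adjusted p 0.0501 to 0.0849). The rises were Phf11d, by 1.27, and Gbp3, by 0.55, both chosen after their values were seen. The Gbp3 call was lost without any single array except GMP replicate B (adjusted p 0.0625 to 0.109) and under quantile normalization (0.00783 to 0.118 over all alternatives). Camera gave adjusted p = 7.19e-07, and adjusted p = 0.472 with an estimated correlation. Of 15 MHC class I presentation genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.29, adjusted p = 0.0142, and adjusted p = 0.409 with an estimated correlation). The median of this list was 0.15 to 0.43 over all alternatives. The call was lost under quantile normalization (adjusted p = 0.0777) and in camera on ranks (0.0595), with 0.000248 to 0.409 over all alternatives. Nlrc5, the transactivator of class I genes, rose by 1.31 (SE 0.18, adjusted p = 0.000931), H2-M3 by 0.72 and H2-D1 by 0.62 (SE 0.10). Tap1, the peptide transporter, rose by 0.68 in its brightest probe set but by 0.15 (adjusted p = 0.24, and 0.00261 to 0.24 over all alternatives) in the mean of its probe sets. Of 9 MHC class II genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.899), against 2 and 0 after median centring. H2-DMa rose by 0.90, a call lost without L-GMP replicate A or GMP replicate B (adjusted p 0.0543 to 0.0585). H2-Oa fell by 0.45, a call lost without any single array except L-GMP replicate C (0.0821 to 0.102) and under both other scalings (0.0123 to 0.163 over all alternatives).

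The list of immediate early and heat shock genes, which respond to stimulation and to handling, was called higher in L-GMPs with the preset correlation, but not with an estimated one. Of 24 measured, 11 rose and 1 fell (14 and 2 adjusted over the list alone), with a median change of 0.86. Klf2 rose by 2.96 (SE 0.42, adjusted p = 0.00115), the AP-1 subunit gene Fosb by 2.90 (SE 0.44) and Klf6 by 1.33 (SE 0.25). Atf3 rose by 2.69, a call lost without GMP replicate B or C (adjusted p 0.0577 to 0.0592). Camera gave adjusted p = 4.63e-06, and adjusted p = 0.472 with an estimated correlation. The mean over the members differed between arrays of a group, from 7.34 in GMP replicate A to 8.15 in GMP replicate D, and from 8.11 in L-GMP replicate B to 9.05 in L-GMP replicate D. The 1 fall was Nr4a2, chosen after its values were seen, by 0.75 (-0.39 in the mean of its probe sets), a call lost without L-GMP replicate A or D or GMP replicate B, C or D (adjusted p 0.0577 to 0.108) and under both other scalings (0.0168 to 0.108 over all alternatives). Of 27 NF-kB and inflammatory genes, 5 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.445), against 8 and 3 under both other scalings. Ccl9, Birc3 and Ccl2 rose by 0.60, 0.51 and 0.53 and Tnfrsf1b fell by 0.59, all chosen after their values were seen. Ccl3 rose by 1.90, a call lost without any single L-GMP array except replicate B or without GMP replicate B or C (adjusted p 0.0549 to 0.0715). Ccl2 lost its call without L-GMP replicate A or C or GMP replicate B or C (0.0608 to 0.0796). Tlr4 fell by 1.59, a call lost without L-GMP replicate A, C or D or GMP replicate B, C or D (0.0624 to 0.113). Means of the probe sets gave -0.97 for Tlr4 and -0.38 for Tnfrsf1b. Nfkbia, the inhibitor of NF-kB, rose by 1.14 (SE 0.21), and Il6 fell by 1.05 near the dim end, at 2.27 ± 0.24 in L-GMPs and 3.31 ± 0.36 in GMPs (SD, n = 4).

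Genes of cell death were led by Pmaip1. Of 13 BCL2 family genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.28, adjusted p = 0.0122, and adjusted p = 0.185 with an estimated correlation). The median ranged from 0.13 to 0.42 over all alternatives. Pmaip1, which encodes the pro-apoptotic protein NOXA, rose by 3.07 (SE 0.35, 8.40-fold, adjusted p = 0.000241). Bmf and Bbc3, which encode pro-apoptotic members, rose by 0.72 and 0.43. The mean of the Bmf probe sets rose by 0.46. Bmf lost its call without L-GMP replicate A or C or GMP replicate B, C or D (adjusted p 0.0516 to 0.0903), and Bbc3 without L-GMP replicate A or C or GMP replicate C (0.0528 to 0.0553). Of 23 p53 target genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.27), against 9 and 1 after median centring and 6 and 2 after quantile normalization. Pmaip1 was among them, and Perp, a membrane protein, fell by 2.76 (SE 0.20). Ccng1 and Zmat3, chosen after their values were seen, rose by 0.54 and 0.45, and Bbc3 and Phlda3 rose as well, Phlda3 by 0.60, while Sesn1 fell by 0.70. Ccng1 lost its call in the mean of its probe sets (change 0.34, adjusted p = 0.0726, and 0.00149 to 0.0726 over all alternatives). Single omissions ended the call of Zmat3 (L-GMP replicate A, C or D, GMP replicate B or C; 0.0554 to 0.0965) and of Phlda3 (L-GMP replicate A, C or D, GMP replicate B, C or D; 0.0574 to 0.0876). They also ended that of Sesn1 (L-GMP replicate A or B, any GMP array; 0.0525 to 0.0768).

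**Figure D3:**
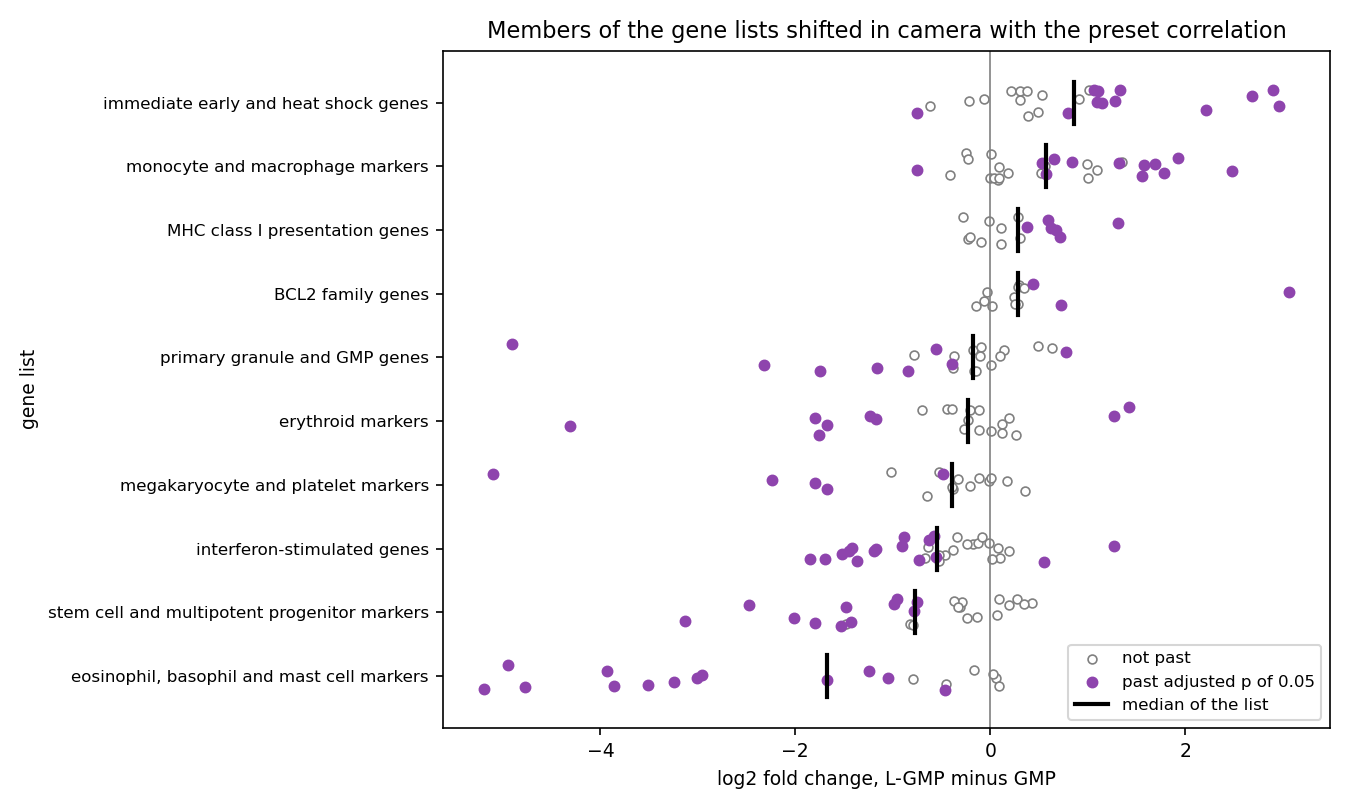
Log2 fold change of L-GMP minus GMP (horizontal axis) for each measured member of the 10 gene lists called by camera with the preset correlation (vertical axis). Filled points passed adjusted p of 0.05 over all genes, open points did not, and black bars are list medians, from -1.68 for eosinophil, basophil and mast cell markers to 0.86 for immediate early and heat shock genes. With an estimated correlation 0 of the 10 lists were called, and under quantile normalization the erythroid and MHC class I lists were not.

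Of 30 DNA replication and S phase genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.27). Ccne2, cyclin E2, fell by 1.02 (SE 0.14, adjusted p = 0.00106). Ccne1 rose by 0.54, a call lost without any single array except L-GMP replicate D (adjusted p 0.0508 to 0.0978). Of 30 G2 and mitosis genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.138). The list, with a median of -0.13, was called under quantile normalization (median -0.18, adjusted p = 0.0152), with every probe set tested (0.0316), on ranks and without L-GMP replicate B and GMP replicate D together (0.0353; 0.0152 to 0.801 over all alternatives), while its median was 0.01 after median centring. The rise was Cenpf, by 0.53, a call lost without L-GMP replicate C, L-GMP replicate D or GMP replicate D (adjusted p 0.0574 to 0.0667) and in the mean of its probe sets (change 0.13, adjusted p = 0.458, and 0.00684 to 0.458 over all alternatives). Of 16 cyclin D, CDK and CDK inhibitor genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.27). Ccnd1, cyclin D1, rose by 1.60 (SE 0.24, adjusted p = 0.00163) and Cdkn2b, an inhibitor of CDK4 and CDK6, by 1.26 (SE 0.24). Cdkn2d rose by 0.57 and Cdkn2c, chosen after its values were seen, by 0.39, while Rb1 fell by 0.66. The Cdkn2d call was lost without L-GMP replicate A or GMP replicate B, C or D (adjusted p 0.0561 to 0.0667). The Cdkn2c call was lost without L-GMP replicate A or C or any GMP array (0.0807 to 0.123), and the Rb1 call without L-GMP replicate A, C or D or GMP replicate B, C or D (0.0561 to 0.0821) and in the mean of its probe sets (change -0.31, adjusted p = 0.264, and 0.00344 to 0.264 over all alternatives). Fry called this list (adjusted p = 0.0432, and 0.0432 to 0.834 over all alternatives). Of 29 MYC and ribosome biogenesis genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.0536, and 0.0276 after median centring, where 9 rose). These were Mycn, with the probe set limit above, and Ppan, by 0.48, a call lost without L-GMP replicate A or C or GMP replicate B or D (adjusted p 0.0638 to 0.0741). The MYC list was also called under the trended robust prior (0.0304), without L-GMP replicate C (0.0414), without GMP replicate C (0.0397) and by fry (0.000101), with 0.000101 to 0.366 over all alternatives.

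Of 25 ribosomal protein genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.63), in which Rpl14 fell by 0.71. Of 18 glycolysis genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.782), the glucose transporter Slc2a1, by 0.86 (SE 0.15, adjusted p = 0.00447). Of 37 mitochondrial respiration genes, 0 rose and 0 fell in limma, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.518). At an unadjusted p under 0.05 there were 6 in limma and 6 in a fit without the prior, of which limma's included 1 rise. The largest change was 0.35 in Cs (adjusted p = 0.109), which passed after median centring (0.0296, and 0.0296 to 0.222 over all alternatives). After quantile normalization 0 rose and 2 fell, and fry called the list lower (adjusted p = 0.0213, and 0.0213 to 0.986 over all alternatives). Of 19 antioxidant genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone; adjusted p = 0.53), among them Gclm, which fell by 0.85, and Nqo1, which fell by 0.67, against 2 and 2 after median centring. Cat fell by 0.47, a call lost after median centring (adjusted p = 0.0689), and Hmox1 rose by 0.45, a call lost without any single array except L-GMP replicate B (0.055 to 0.102). Of 20 FOXO target genes, 3 rose and 3 fell (5 and 7 adjusted over the list alone; adjusted p = 0.738), namely Klf2, Klf6 and, chosen after its values were seen, Pik3ip1 by 0.71, and Selenop, Sesn1 and Bcl6. After median centring 4 rose and 2 fell. Selenop fell by 1.55 (SE 0.19) and Bcl6 by 0.82. Bcl6 lost its call without L-GMP replicate C or GMP replicate B, C or D (adjusted p 0.0524 to 0.0832), and Sesn1 without L-GMP replicate A or B or any GMP array (0.0525 to 0.0768). Of 12 housekeeping genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone; adjusted p = 0.762). Gusb rose by 0.42 and Tbp fell by 0.38. After median centring 1 rose and 0 fell, and after quantile normalization 0 rose and 2 fell. The Gusb call was lost without any single array except L-GMP replicate D (adjusted p 0.0516 to 0.0915), and the Tbp call without L-GMP replicate A, C or D or GMP replicate B, C or D (0.0575 to 0.0814).

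Of 33 chromatin and DNA methylation regulators, 2 rose and 7 fell (4 and 9 adjusted over the list alone; adjusted p = 0.242). After median centring 6 rose and 4 fell (median 0.06 in place of -0.08), so the balance depends on scaling, and of the alternatives only fry called the list (adjusted p = 0.00402, and 0.00402 to 0.478 over all of them). Kdm5b, a histone H3K4 demethylase, fell by 4.16 (SE 0.21, 17.9-fold, adjusted p = 3.96e-07), or -2.32 in the mean of its probe sets, Tet1 by 1.78 (SE 0.17) and Mllt3 by 1.48, while Tet2 rose by 0.78 (SE 0.14) and Kdm6b, chosen after its values were seen, by 0.50, a call lost without L-GMP replicate B and GMP replicate D together (adjusted p = 0.0558, and 0.00208 to 0.0558 over all alternatives). Of 22 leukaemia stem cell surface antigens, 3 rose and 6 fell (6 and 6 adjusted over the list alone; adjusted p = 0.79), against 6 and 4 after median centring and 4 and 4 without the dimmest 25% of genes. Adgrg1 (GPR56) fell by 2.28 (SE 0.25) and the tetraspanin Cd9 fell by 1.89 (SE 0.14). Cd244a rose by 1.61 (SE 0.18), Cd33 by 1.14 and Pecam1, chosen after its values were seen, by 0.75. Of 24 adhesion and homing genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.762). The chemokine receptor gene Ccr1 rose by 3.13 (SE 0.23, adjusted p = 9.09e-06) and Cdh1, E-cadherin, fell by 2.50 (SE 0.19). The GMP mean of Ccr1 (3.56) lay below the lower quartile of every array (3.65 to 3.75), so the size of its rise is uncertain. The other rises, chosen after their values were seen, were Itgb2 by 1.14 and Ccr2 by 0.53. Ccr2 lost its call without L-GMP replicate A, C or D or GMP replicate A, C or D (adjusted p 0.0519 to 0.078), and its rise was 0.09 (adjusted p = 0.817, and 0.00546 to 0.817 over all alternatives) in the mean of its probe sets. Of 31 Wnt pathway and target genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p = 0.738), against 3 and 3 under both other scalings. Ccnd1 was among the rises, and Bcl9, a coactivator of beta-catenin, and Tcf7l2 fell by 1.11 (-0.74 in the mean of its probe sets) and 0.90. Tle1 fell by 1.52, a call lost without GMP replicate D (adjusted p = 0.0553), with -0.98 when L-GMP replicate B and GMP replicate D were left out together. Nkd1 rose by 0.34 and Fzd6 fell by 0.57, both chosen after their values were seen. Their calls were lost without L-GMP replicate A, B or C or GMP replicate B, C or D (Nkd1, 0.0736 to 0.106) and without L-GMP replicate A, C or D or GMP replicate B, C or D (Fzd6, 0.0549 to 0.104), and in the mean of its probe sets Nkd1 rose by 0.19 (adjusted p = 0.183, and 0.0125 to 0.183 over all alternatives). Of 18 Notch pathway genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.762). After median centring 2 rose. The 1 rise was Rbpj, by 0.43, a call lost without L-GMP replicate A, C or D or GMP replicate B, C or D (adjusted p 0.0705 to 0.0955). In 8 lists the median, the mean and the camera direction did not share a sign, namely the HOXA9 and MEIS1 targets, MHC class II, B lymphoid, endothelial, leukaemia antigen, Wnt, glycolysis and FOXO lists.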

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

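No test in this part was chosen after its result was seen, except that genes named after their values were seen are among those whose arrays were compared. In 374 groups of 4 arrays, 31 values stood far from the other 3, where chance gives about 1 in 20.

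In L-GMP replicate B, Xist, the RNA of the inactive X chromosome, was 3.77, against 12.2 to 12.4 on the other L-GMP arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty were together higher by 4.309 on this array than the mean of the other 7 arrays, which is what cells of a male animal would give, and this may account for the value. Loss of the inactive X in cells of a female animal is argued against, since these genes exceeded the highest of the other 7 arrays by 4.141. Sex is not given by the labels, and no other array had the male pattern, so sex and other differences between the animals behind this array stay open.

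Further values of L-GMP replicate B stood apart. Igf2bp3 was 8.73 (others 10.5 to 10.8), Nkg7 7.2 (5.29 to 5.58), Tle1 3.43 (4.93 to 5.15), Hoxb3 3.64 (3.87 to 3.91) and Vwf 4.78 (4.29 to 4.32). Hbb-b2 was 3.61 (3.35 to 3.37), Bbc3 6.04 (6.28 to 6.31), Ptch1 6.18 (3.57 to 3.84) and Hdc 8.23 (6.62 to 6.76).

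On the other L-GMP arrays, Ppic was 3.65 in replicate A (4.03 to 4.08 on the others), Ptger4 3.28 in replicate A (4.89 to 5.12), Prg2 6.37 in replicate C (4.44 to 4.72) and Car2 5.26 in replicate D (4.18 to 4.35). Zmat3 was 5.55 in replicate D (5.18 to 5.22). A control probe set for the 5' part of 18S ribosomal RNA was 12.52 in replicate D (13.08 to 13.19). Among GMP arrays that probe set ran from 10.71 in replicate D to 13.09 in replicate A, with 12.52 in replicate B.

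In GMP replicate A, Cd68 was 6.7 (6.87 to 6.89 on the other GMP arrays), Mpeg1 8.78 (9.21 to 9.26), H2-M3 9.42 (9.8 to 9.81), Adgrg1 8.99 (8.69 to 8.73), Cd33 5.3 (4.79 to 4.87), Tlr4 7.33 (7.95 to 8.02) and Phlda3 4.48 (3.97 to 4). In GMP replicate C, Cxcr2 was 6.39 (6.67 to 6.7), H2-D1 11.56 (11.46 to 11.47), Cav1 4.27 (4.55 to 4.57) Sesn1 8.67 (8.78 to 8.81) and Kdm6b 7.45 (7.22 to 7.25). In GMP replicate D, Colec12 was 2.17 (2.4 to 2.43), Birc3 8.52 (8.33 to 8.37) and the control probe set for the 3' part of 18S ribosomal RNA 11.93 (13.72 to 13.9).

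Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave 2193 genes past the threshold, and the highest of the others gave 1. For changes of at least 2-fold, the real split gave 690 genes and the highest other 1, again with 1 split as large. The real split was thus 1 of 35 for both counts, the smallest share these splits can give. Every other split mixes the groups, so few calls follow there whatever set the groups apart, and a batch is not excluded.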

How the results depend on the processing

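All settings here except the omission of L-GMP replicate B and GMP replicate D together were chosen before the data were examined, and that pair was left out after seeing the data. It gave 1557 genes, of which 1359 were among the 2193. Over all settings, the 181 named genes kept their side of the threshold 2881 times, lost the call 312 times, gained it 2 times and reversed 2 times, and the 37 lists did so 729, 22, 20 and 1 times. Among those kept, all but 10 for genes and 59 for list medians also kept their sign, and these exceptions were not called. Of 167 named genes past the threshold, 122 stayed past it whichever single array was left out. Centring each array on its median gave 2161 higher genes, since it shifted the median of all genes to 0.15. Leaving out the dimmest 50% of genes gave 374 genes at least 2-fold changed, 216 of them lower, from fewer genes tested. The erythroid median turned to 0.16 there (adjusted p over all alternatives 0.00751 to 0.784). This filter used the mean over all 8 arrays and so left out the fallen members Car1, Hbb-b2 and Gata1 (percentiles 30.7, 27.5 and 42.7). The fallen Car2 and the risen Mt1 and Mt2 stayed (57.6, 91.0 and 60.4). How much of the turn this accounts for was not tested. The mean of a gene's probe sets gave -0.92 for Hoxa9 and -0.0133 for Hmga2, because their probe sets disagree. Testing every probe set gave 4921 (1754 higher, 3167 lower), and 1517 at least 2-fold changed (400 and 1117), from more probe sets tested. Without the prior there were 1137 genes (459 and 678; the cause was not tested), and treat gave 389 (99 and 290), by its stricter null. Camera with an estimated correlation called 0 lists (smallest adjusted p 0.0536), against 10 with the preset one.

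Leaving out 1 array at a time gave 1411 (without GMP replicate B) to 2388 (without GMP replicate A) genes, with 514 (without GMP replicate C) to 942 higher and 868 to 1446 lower. GMP replicate B gave 543 higher and 868 lower, and GMP replicate D 1425, with 550 and 875. At least 2-fold changes numbered 625 to 790 (177 to 254 higher, 441 to 536 lower), lists 9 to 12, Hoxa9 4.60 to 5.07 and Meis1 -3.26 to -2.90. With the letter as a replicate block there were 1760 genes, of which 1659 were among the 2193. Deviations of same-letter arrays had correlations across genes of -0.046, -0.009, -0.067 and 0.112 for A to D. What the letters share stays unknown. No signal over background was used, so how far it limits dim genes is unknown.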

Other observations

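The tests of swapped and of exchanged labels, of the construct sequence and of the share of lineage cells were chosen after the result was seen.

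Some genes that changed strongly were picked from further pathways after their values were seen, and these pathways were not tested as groups. Beside Smo, Ptch1, the Hedgehog receptor and a target of the pathway, fell by 4.08 (SE 0.49, adjusted p = 0.000356) in its brightest probe set and by 1.35 in the mean of its probe sets, with L-GMP replicate B at 6.18 above the other L-GMP arrays. Beside the rise of Hpgd, the prostaglandin E2 receptor genes Ptger3 and Ptger4 fell by 4.36 (SE 0.24, adjusted p = 9.78e-07, and -2.84 in the mean of the Ptger3 probe sets) and 3.47 (SE 0.36, adjusted p = 0.000118), while the prostacyclin receptor gene Ptgir rose by 1.71 (SE 0.30, adjusted p = 0.00464). Beside F7, coagulation factor X (F10) rose by 2.31 (SE 0.27, adjusted p = 0.00029), while F2r, a thrombin receptor, fell by 4.33 (SE 0.36, adjusted p = 2.34e-05) to an L-GMP mean near the floor (2.41). In these 6 genes the groups did not overlap, as in 18.2% of all genes. The 6 were picked with their values in view, so this adds no support.

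The Hoxa9 probe sets moved in opposite directions, by 4.82 and -6.66. Swapped labels of some but not all arrays of a group are argued against, since the lowest L-GMP value of the risen probe set exceeded the highest GMP value by 4.027, more than the largest spread within a group, 1.428. Exchanged labels of the whole groups would leave that gap as large, and with a change of -6.66 in the dimmer probe set they cannot be told apart from the labels as given by these genes. A candidate explanation is that the risen probe set reads an introduced Hoxa9 while the resident locus was lower, but only 2 other Hoxa genes were bright enough in GMPs, with a median change of -0.977, between the bounds set beforehand (below -1 for it, above -0.5 against it). This and other explanations therefore cannot be told apart for lack of probe positions, and the leukaemia itself stays open as untested.

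The brightest Mycn probe set rose by 8.37, while the others changed by 0.37 and -1.63, the last near the dim end in L-GMPs (3.64), so whether the whole transcript rose stays open. The risen Mycn and Hoxa9 probe sets ranked the 4 L-GMP arrays in the same order (4 of 4 ranks alike, as in 1 of 24 orders). This order was compared after the values were seen, and many other genes can share it. Ptgir did, with 8.77 in replicate B, 8.35 in C, 8.02 in A and 7.33 in D. The shared order therefore does not bear on whether both probe sets read a sequence of an introduced construct. With 4 arrays and no probe sequence, that cannot be told apart from a transcript of the resident Mycn gene that begins or ends elsewhere.

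The erythroid, megakaryocyte and eosinophil, basophil and mast cell lists held 23 different members that fell. Lower RNA quality of GMP replicate D is argued against as the whole cause, since 18 of the 23 stayed past the threshold without that array. The members had a median SD of 0.549 among GMP arrays, against 0.189 in other falling genes matched on GMP level (permutation p = 1e-04, the smallest that 10000 draws can give). The draws did not match the size of the fall, and a large fall can pass the threshold with a large SD. They also treated genes that vary together over the GMP arrays as independent. The test cannot decide whether the share of cells of these lineages varied between the GMP sorts, for example of eosinophils in GMP replicate B. Gata1 (SD 0.105) and Car2 (0.188) varied less among GMP arrays, as did Hdc (0.185), Slc18a2 (0.258) and Csrp3 (0.278), chosen after their values were seen. Gp5 (0.136) and Cma1 (0.07), also chosen after their values were seen, fell by only 0.49 and 0.47. Falls that small pass the threshold only with a small SD, so neither SD bears on the share of cells. The Cma1 call was lost under both other scalings (adjusted p 0.0353 to 0.153 over all alternatives) and without any single array except L-GMP replicate A (0.0599 to 0.111). Epx was highest (10.9) and Pf4 lowest (7.20) in GMP replicate B, so a share of 1 cell type alone would not give both. Among abundant members, Ms4a2, Hba-a2 and Itgb3 had GMP means of 10.3, 11.4 and 9.07 and changes of -4.95, 0.19 and 0.36, and levels of different probe sets do not compare amounts. Gata1 belongs to both the erythroid and the eosinophil, basophil and mast cell list. The sort for GMPs would be meant to remove mature cells, and a true loss of these programmes in L-GMPs stays open.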
